A study of Arabidopsis thaliana with 156 samples.

How the data were processed

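Gene expression was measured in polyA RNA that had been labelled with biotin and hybridised to oligonucleotide arrays, 1 array per replicate. Plants grew on 16 h days, and their age was counted from the transfer of the flats to the growth chamber. Every replicate combined RNA from collections at 3 times of 1 day, so the arrays of a group are separate pools of organs. A replicate held between 24 and 120 shoot apices, 30 primordia (60 for leaves 1/2) or 9 leaves (18 for leaves 1/2). The 156 arrays formed 53 groups defined by genotype, organ, day or leaf position, and experiment. Replicate numbers recur across groups, and whether they pair the arrays was checked rather than assumed.

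The values analysed are the deposited ones, a log2 value per probe set and array, which the authors had brought to a common scale across arrays. GCRMA and MAS5 are named in the submitters' processing notes, and their versions, and any filter on probe sets, are not given in the sources used here. Nothing was added to the values or rescaled before the tests, and all 19324 probe sets of all arrays entered them. Array medians ranged from 6.40 to 6.92. Signal on an array holds no count of molecules, so precision is given by the replicates, and simulated changes were used to express it.

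Probe sets were named from a table of probe sets and genes. It listed 11325 of the probe sets, 10918 of them with 1 gene and 407 with several, and 7999 were not listed. Those 10918 named 10786 genes, of which 1401 have a symbol other than the locus tag. FLC, SOC1, FT, SPL3, SPL4, SPL5, SPL9 and SPL15 were part of the rule for naming genes and were not analysed here. Gene lengths, the span from start to end of each gene in the TAIR10.1 assembly, were held for 10766 of the genes (99.8%) and served only to look for trends with length.

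Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, to 4 sets of arrays. These were the apices (30 arrays, 11 groups), the primordia (36, 12), the expanded leaves and leaves past full expansion (90, 30), and for the comparison of leaf stages the primordia and expanded leaves of experiment 1 (72, 24). Contrasts were tested with moderated t statistics, two-sided, with a prior variance that follows the mean signal (eBayes with trend). The p values were adjusted by the Benjamini-Hochberg method over all probe sets, and a probe set was called at an adjusted p under 0.05. Contrasts over several days, positions, genotypes or experiments are means of the differences within each of these strata. A group of 2 arrays and the single array of FRI;flc-3 apices at day 6 are assumed to vary like the other groups of their fit.

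The comparisons, the lists of expected genes, the rule for naming genes and the other settings tried were chosen before the data were examined. In each comparison the rule names the 6 largest positive and the 6 largest negative differences among called genes with the same sign in every stratum. Where a comparison has 1 stratum, the arrays of its groups had to be without overlap instead. For genes named for their size, a shared sign or a lack of overlap was thus required. It is no separate evidence where it is given below. It also names the 3 members with the largest absolute difference of each called gene list. Of several probe sets of a gene, the one with the highest mean over all arrays was used. Genes chosen only after their values were seen are marked so. Probe sets matched to several genes and control probe sets (41) were tested and not named.

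Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes and 1 probe set per gene. Adjustment was over the lists of a comparison, and lists with fewer than 3 measured genes were not tested. Of 26 lists fixed beforehand, with 369 genes, 43 genes were measured, and 8 lists could be tested: cell cycle, flavonoid, floral transition, glucosinolate, photosynthesis, senescence, stomata and trichome genes. Of the 26 lists, 9 had 0 members among the genes named here. The lists tested held 3 of 29 cell cycle, 3 of 17 flavonoid, 5 of 20 floral transition, 3 of 24 glucosinolate and 4 of 28 photosynthesis genes. They also held 4 of 21 senescence, 4 of 8 stomata and 3 of 18 trichome genes. A list result therefore covers the measured members and not the whole pathway. A further 26 lists were added from the gene names after the table of names was seen and before expression was compared, and were adjusted separately. The results of 1 added list are not reported here, although it took part in the adjustment and in the totals of list tests and calls. The tests were repeated with the correlation estimated from the arrays and on the probe sets with a mean signal above the median.

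The other settings, each changing 1 choice, were quantile normalization, the probe sets with a mean signal above the median, omission of probe sets with several genes, a prior variance without trend, a robust prior (with statmod 1.5.0), array weights and the replicate number as a block. Others were a fit of only the groups compared, omission of each replicate in turn, day 6 in the apex genotype comparison, each experiment or genotype alone, and a linear trend over 5 leaf positions. Chosen after the data were seen were the mean of days 4 and 9 as the control of the mimic line, fits without the day 6 arrays of FRI;FLC and FRI;flc-3, the genotype comparison of primordia over 5 rosette positions, fits without the third replicates of FRI;FLC leaves 9 and 11 of experiment 1, and the removal from each array of its trend on log10 gene length (natural spline with 4 degrees of freedom).

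The models were tested on simulated data in which 200 of 19324 probe sets changed. With a change of 1 log2 unit, 91% were recovered in the apex genotype comparison, 43% for the mimic line, 18% for the difference of age changes between genotypes, 100% for genotype in expanded leaves and 50% for the difference of position changes there. With a change of 0.5 units the recovery was 46%, 2%, 3%, 87% and 14%. False calls numbered between 1 and 16. The simulated noise was independent between probe sets, whereas leaf arrays of a group deviated together along 1 axis (34.7% of the variance within groups). These figures therefore do not give the recovery or the false calls to be expected with such shared deviations. For each comparison of at least 3 arrays against 3, the calls were also counted for other splits of the arrays within their strata, at most 100 per comparison. For the differences of changes these splits were repeated after removal of the effect common to both ends, a step added after the counts were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.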

Results

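The transcriptomes of shoot apices, leaf primordia and leaves of Arabidopsis thaliana were measured on arrays in plants that carry a functional FRI gene together with either functional FLC (FRI;FLC) or the flc-3 allele (FRI;flc-3). FRI raises the activity of FLC, a repressor of flowering, so FRI;FLC plants remain vegetative for longer and form more rosette leaves. A separate line in the FRI;FLC background expressed a miR156 target mimic from the 35S promoter, an RNA that binds miR156 and lowers its activity. The series held 156 arrays in 53 groups, and each array was hybridised with RNA from a separately collected pool of organs. There were 51 groups of 3 arrays, 1 group of 2 arrays (FRI;FLC apices at day 6) and 1 group of 1 array (FRI;flc-3 apices at day 6). The genotypes were represented by 80 arrays of FRI;FLC, 73 of FRI;flc-3 and 3 of the mimic line.

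Shoot apices with primordia shorter than 1 mm came from FRI;FLC plants of 4, 6, 9, 11, 14 and 21 days, from FRI;flc-3 plants of 4, 6, 9 and 11 days and from mimic plants of 6 days, in 30 arrays. Leaf primordia of 1 mm came from the odd leaf positions 3 to 11 and from leaves 1/2 (the first pair) of both genotypes, in 36 arrays. Fully expanded leaves of the same positions came from 2 experiments, the primordia sharing their plants with experiment 1 and the apices with experiment 2, and leaf 11 of FRI;flc-3 was a cauline leaf, a leaf of the flowering stem. In experiment 2, leaves 3, 5 and 7 were also collected past full expansion, on the day when leaf 9 was fully expanded. Leaves on 16 h days were taken as fully expanded when they lengthened by less than 1 mm on 2 consecutive days. Array medians lay between 6.40 and 6.92 log2 units and single values between 0.30 and 13.99. The median correlation between arrays of 1 group was 0.992 and the highest between any 2 arrays was 0.998, and 0 pairs were identical. The 2 FRI;FLC day 6 apex arrays correlated at 0.954, lower than any other apex group (0.978 or more). Across all arrays, 10% of values lay below 2.03, so the size of log2 differences with a level near 2, as for AT1G69480, AGL42, AGL24 and EXPA8, is uncertain. Because array signal holds no count of molecules, the number of arrays sets the precision of what follows. The standard errors and p values measure the spread among pools of a group within 1 experiment, not the variation between experiments. Apices, primordia and leaves past full expansion were each sampled in 1 experiment only.

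Of the 19324 probe sets tested, 10918 could be assigned to 1 gene, which named 10786 genes, and probe sets outside the naming table are given by their identifier alone. Differences are log2 values ± standard errors of the limma model and p values are two-sided, adjusted over all probe sets unless stated. The direction is FRI;flc-3 minus FRI;FLC, older minus younger plants, and upper minus lower leaf position. FLC, SOC1, FT and the miR156 targets of the SPL family were not analysed here. How well the labelled polyA RNA measures plastid-encoded transcripts was not tested, so plastid-encoded genes are given as array signal only. Of 160 tests of the gene lists fixed beforehand, 37 were called, and 24 of those also with an estimated correlation between genes. Of 520 tests of lists added later, 100 were called and 10 held with that estimate. In each called list, the median, the mean and the test had the same sign.

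**Figure D1:**
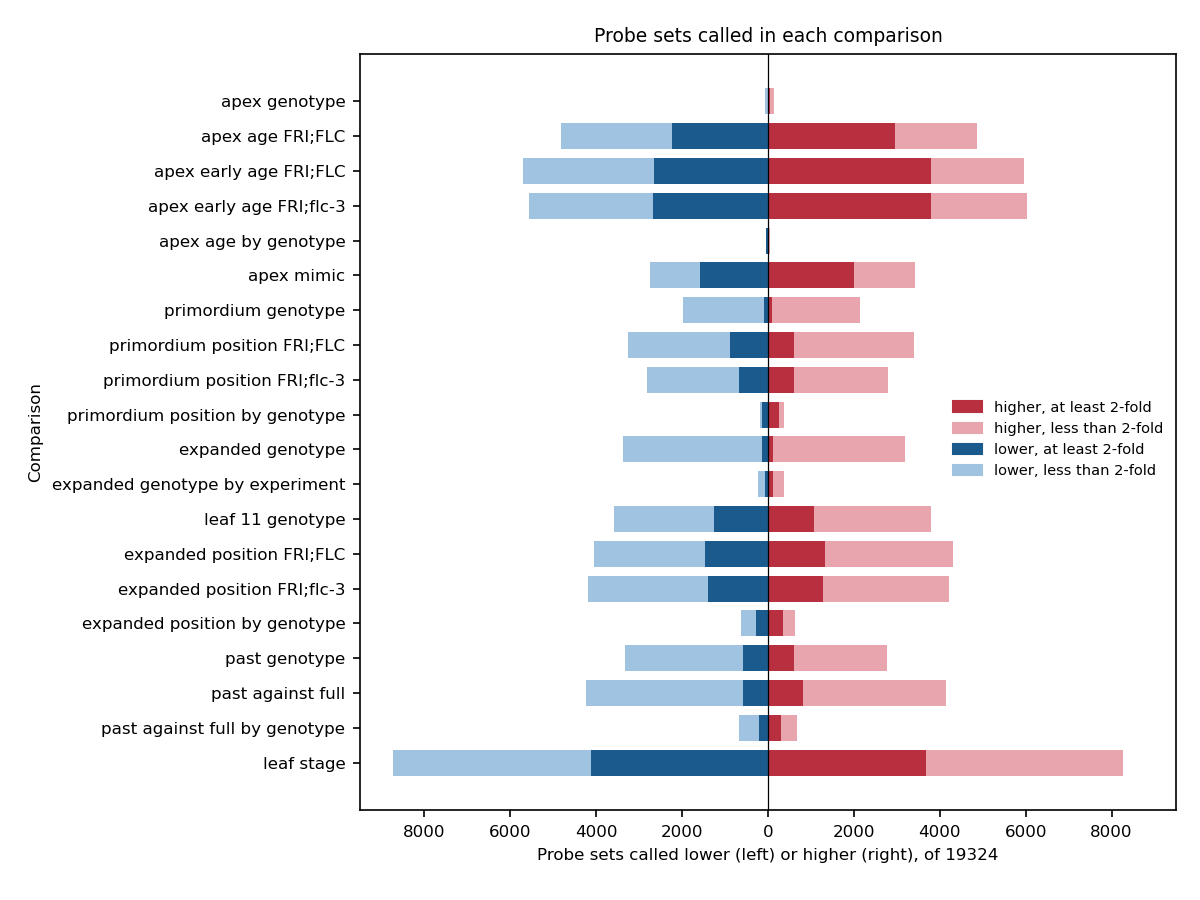
Probe sets called at an adjusted p under 0.05 in each comparison (bars to the right, higher, to the left, lower, dark parts, at least 2-fold; x axis, number of probe sets of 19324). Leaf stage called 8260 higher and 8743 lower, and genotype in apices 143 higher and 73 lower.

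Genotype in shoot apices was compared at days 4, 9 and 11, with 9 arrays of each genotype. The largest named difference was AT1G69480, which stood at 7.14 in FRI;flc-3 and 2.31 in FRI;FLC, a difference of 4.83 ± 0.17 (adjusted p = 1.79e-17, higher on all 3 days). AGL24 (AT4G24540), a MADS-box gene that promotes flowering, was higher by 1.07 ± 0.19 (adjusted p = 0.00176, all 3 days), and AT4G34400 was higher by 2.34 ± 0.23. FD (AT4G35900), which encodes the bZIP partner of FT, was higher by 0.76 ± 0.15 on 2 of 3 days, but its adjusted p was 0.0584 without replicate 1 and 0.221 without replicate 3. COR15B, a cold-responsive gene, was higher by 1.00 ± 0.16 (adjusted p = 0.00041). AT2G43600 was lower, at -1.60 ± 0.20, and DFR (AT5G42800), the dihydroflavonol reductase gene of anthocyanin synthesis, at -0.82 ± 0.16. DFR reached an adjusted p of 0.0762 without replicate 1 and 0.277 without replicate 3. Among the probe sets unnamed here, 267509_at differed by 4.82 ± 0.15 and 260037_at by -4.61 ± 0.19.

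Of the floral transition genes, 2 were higher in FRI;flc-3 apices and 3 not called (3 higher when adjusted over the list alone, list adjusted p = 1.76e-06, and 0.00321 with an estimated correlation). Among the flavonoid genes 1 was lower and 2 were not called (3 lower when adjusted over the list alone, adjusted p = 0.000228 and 0.00827). Of the cold and dehydration genes added later, 2 were higher (COR15B and LTI30) and 10 not called, and the list call was lost with an estimated correlation (adjusted p = 0.144), as was that of the SWEET sugar transporter genes (2 higher, 10 not called, adjusted p = 0.01 and 0.318). LTI30 differed by 1.80 ± 0.30, with an adjusted p of 0.133 without replicate 1. In all, 143 probe sets were higher and 73 lower, of which 43 and 9 differed at least 2-fold. Among the probe sets with a mean signal above the median, 29 were higher and 36 lower. The counts rose to 267 higher and 197 lower with array weights. A fit without the day 6 arrays of FRI;FLC and FRI;flc-3 gave 217 and 141. Among genes with a length, 51 were higher and 18 lower, and 45 and 29 once each array's trend on length was removed. The total of 216 changed to 104 without replicate 1 and 56 without replicate 3.

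The change of FRI;FLC apices with plant age was taken from day 4 to day 21, with 3 arrays at each age. AGL24 rose by 5.76 ± 0.33, from 3.97 to 9.73, AGL42 (AT5G62165), a MADS-box relative of SOC1, by 2.49 ± 0.32 and FD by 1.51 ± 0.26. The peptidase gene scpl31 rose by 7.38 ± 0.23 and the jacalin lectin gene JAL23 by 7.24 ± 0.38, while AT1G67865 rose by 9.47 ± 0.53. The MADS-box gene AGL87 fell by 7.17 ± 0.24, the methionine sulfoxide reductase gene MSRB6 by 6.15 ± 0.35, the stomatal lineage regulator MUTE by 2.85 ± 0.20 and the leaf blade regulator JAG by 2.65 ± 0.39. For each of these genes, all 3 arrays of 1 age lay outside the range of the other, which a random split of 3 against 3 gives in 10% of cases. The naming rule required this of the genes named for their size. The adjusted p of these 10 genes ranged from 1.75e-19 for scpl31 to 2.25e-05 for FD.

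Of the stomata genes, 0 were higher at day 21, 3 lower (MUTE, STOMAGEN and SPCH) and 1 not called (list adjusted p = 0.0128, and 0.0374 with an estimated correlation, and 3 lower when adjusted over the list alone). SPCH, at -1.16 ± 0.35, had an adjusted p of 0.074 without replicate 1. Among the plastid-encoded photosynthesis genes 35 were lower and 8 not called (petN, -3.93 ± 0.63; petG, -2.88 ± 0.48), and among the nuclear ones 18 were lower and 10 not called (NdhL, -4.19 ± 0.31), but neither list was called with an estimated correlation (adjusted p = 0.451 and 0.186). Of the cell division genes 16 were lower and 12 not called (HTR12, the centromeric histone gene, -1.56 ± 0.15; adjusted p = 0.185 with an estimated correlation). Of the shoot organ regulators 5 were higher, among them PTL at 2.47 ± 0.35 and CYP78A9 at 3.88 ± 0.30, and 17 lower (adjusted p = 0.144 with that estimate). Floral transition genes were called upward with 3 higher and 2 not called (adjusted p = 0.017), and not with an estimated correlation (0.116). In total, 4861 probe sets were higher and 4825 lower, and the number of apices per replicate also differed with age, from 120 at day 4 to 24 at day 21.

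Between day 4 and day 11, an interval measured in both genotypes, several genes with large changes were named in each of them. AGL24 rose by 5.04 ± 0.33 and 4.71 ± 0.33 in the respective genotypes, scpl31 by 6.46 ± 0.23 and 5.93 ± 0.23, and the petal and organ boundary gene PTL by 3.29 ± 0.35 and 2.52 ± 0.35. MSRB6 fell by 5.61 ± 0.35 and 5.77 ± 0.35, the expansin gene EXPA8 by 4.50 ± 0.40 and 5.09 ± 0.40, and the sugar transporter genes SWEET16 by 4.87 ± 0.53 and 3.87 ± 0.53. In FRI;flc-3, AGL42 rose by 3.22 ± 0.32, FD by 2.62 ± 0.26 and AT4G34400 by 5.43 ± 0.40, and the meristem peptide gene CLV3 fell by 3.08 ± 0.25. Adjusted p values of these genes were at most 1.53e-06 for the changes in FRI;flc-3 and 4.28e-08 in FRI;FLC.

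The list of plastid-encoded photosynthesis genes fell in signal in both genotypes over this interval. It gave 1 higher, 33 lower and 9 not called in FRI;FLC and 2, 30 and 11 in FRI;flc-3. Neither this list nor the 2 that follow were called with an estimated correlation (lowest adjusted p = 0.339 in FRI;FLC and 0.215 in FRI;flc-3). The changes from day 4 to day 11 also ran with gene length (Spearman 0.412 and 0.451), and of the 6508 and 6446 calls among genes with a length, 4777 and 4508 were also made with each array's trend on length removed. The array slopes on length were all negative at day 4 (-0.625 to -1.18) and all positive at day 11 (0.711 to 0.971). Expansin, xyloglucan transferase and glucanase genes gave 4 higher, 16 lower and 12 not called, and 3, 18 and 11. Ubiquitin conjugation and protease genes were higher in 13 cases in each genotype (UBP15 by 3.27 ± 0.41 and 3.04 ± 0.41), with 10 and 9 not called. The floral transition list was called in FRI;flc-3 (3 higher, 2 not called, adjusted p = 0.0208, and 0.178 with an estimated correlation) and missed the threshold in FRI;FLC (4 higher, 1 not called, adjusted p = 0.0786). In total 5957 probe sets were higher and 5716 lower at day 11 in FRI;FLC, and 6038 and 5557 in FRI;flc-3.

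The change from day 4 to day 11 differed between the genotypes for 92 probe sets, 36 more positive and 56 more negative in FRI;flc-3. The change was more negative in FRI;flc-3 for the dehydrin gene LTI30 (-4.21 ± 0.73), the cold gene COR15A (-2.34 ± 0.45), the calmodulin-like gene CML38 (-2.50 ± 0.41) and the senescence-associated gene SAG29 (-1.45 ± 0.26). It was more positive for AT4G34400 (3.30 ± 0.57), the wax ester synthase gene WSD1 (2.40 ± 0.47), MUTE (1.52 ± 0.28) and AT5G44630 (2.00 ± 0.22, adjusted p = 3.17e-05). Each of these genes except AT5G44630 lost its call when some 1 replicate was left out, with adjusted p values of 0.188 for LTI30, 0.14 for COR15A, 0.0773 for CML38, 0.126 for SAG29, 0.111 for AT4G34400, 0.232 for WSD1 and 0.174 for MUTE at their highest. The total changed to 31 without replicate 1, 25 without replicate 2 and 8 without replicate 3. Cold and dehydration genes were called downward (0 higher, 2 lower, 10 not called, adjusted p = 0.00612, and 0.217 with an estimated correlation), as were senescence genes (0 higher, 1 lower, 3 not called, adjusted p = 0.0139 and 0.144, and 2 lower when adjusted over the list alone) and calmodulin-like genes (0 higher, 1 lower, 6 not called, 0.00273 and 0.215). Stomata genes were called upward (1 higher, 0 lower, 3 not called, 0.0139 and 0.0678, and 1 higher over the list alone), as were cell cycle genes (0 higher, 0 lower, 3 not called, 0.0139 and 0.0855, and 1 higher over the list alone).

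**Figure D2:**
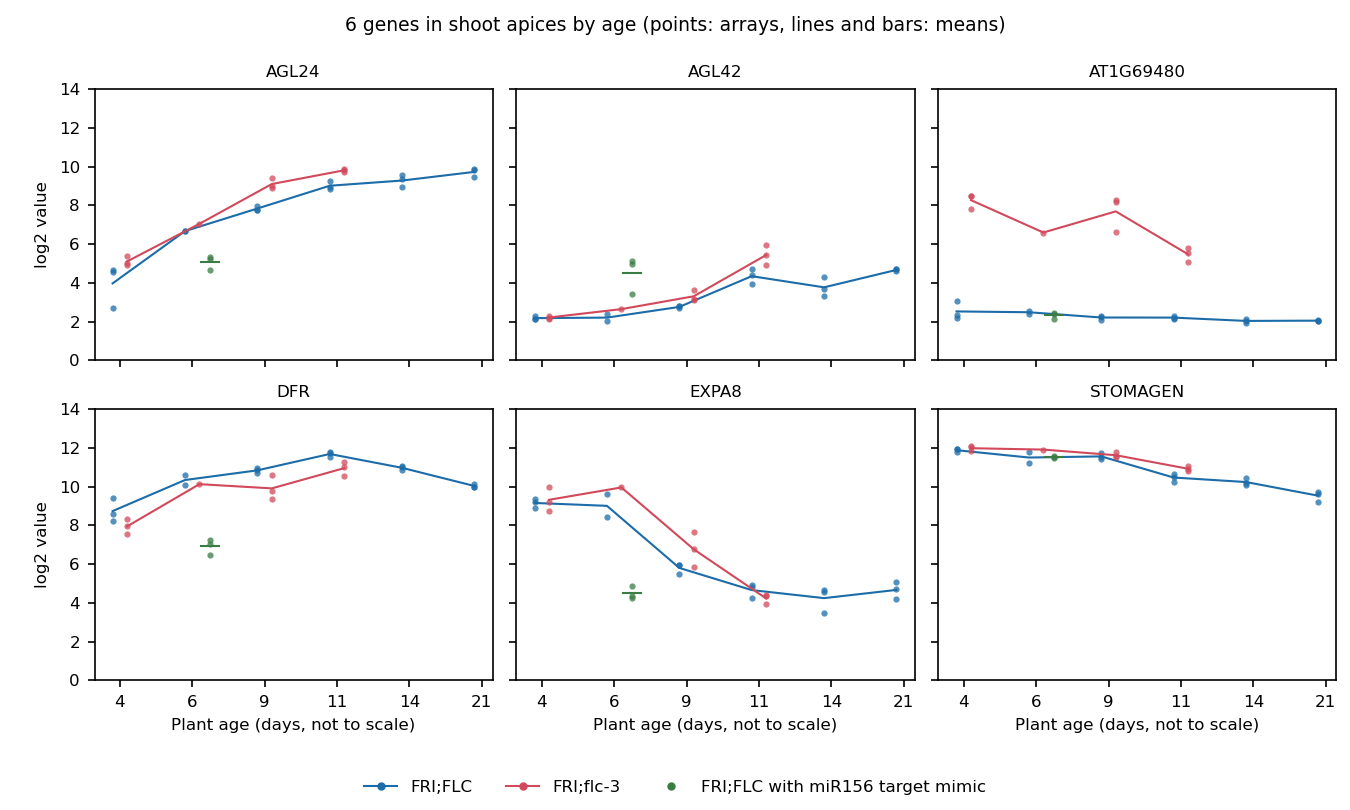
Log2 values of 6 genes in shoot apices against plant age in days (points, arrays; lines and short bars, group means; blue, FRI;FLC; red, FRI;flc-3; green, miR156 target mimic). AGL24 rose from 3.97 at day 4 to 9.73 at day 21 in FRI;FLC, and EXPA8 averaged 4.49 in the mimic line against 9.01 in FRI;FLC at day 6.

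Apices of the miR156 mimic line were compared with FRI;FLC apices at day 6, 3 arrays against 2, to ask what lowering miR156 activity changes. Of genes for glucosinolate and anthocyanin synthesis, the few measured were lower in the mimic (3 of 24 listed glucosinolate and 3 of 17 listed flavonoid genes). BCAT4, which acts in methionine chain elongation, differed by -5.23 ± 0.25 (adjusted p = 6.23e-15), AT2G31790 by -1.29 ± 0.24, DFR by -3.42 ± 0.31 and UF3GT by -2.99 ± 0.40. The lectin gene JAL33 differed by -6.54 ± 0.34, EXPA8 by -4.52 ± 0.45 and EXLB1 by -4.96 ± 0.50. Higher in the mimic were AT4G34400 (6.07 ± 0.45), the cytochrome P450 gene CYP71B22 (5.88 ± 0.22), WSD1 (5.17 ± 0.37) and COR15B (4.67 ± 0.30). In each of these genes the 3 mimic arrays lay outside the range of the 2 control arrays, which chance gives in 20% of splits of 3 against 2.

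All 3 flavonoid genes and all 3 glucosinolate genes were lower in the mimic (adjusted p = 0.000359 for either list, and 0.0103 and 0.00577 with an estimated correlation, and 3 lower in each when adjusted over the list alone). Of the glucosinolate genes, AOP3 (-0.74 ± 0.19) had an adjusted p of 0.245 without FRI;FLC replicate 1. Photosynthesis genes gave 2 higher, RCA (1.05 ± 0.18) and SBPASE (1.03 ± 0.20), and 2 not called, with 3 higher when adjusted over the list alone (adjusted p = 0.0299, and 0.176 with an estimated correlation); SBPASE had an adjusted p of 0.137 without FRI;FLC replicate 1. Cell wall expansion genes gave 0 higher, 11 lower and 21 not called (adjusted p = 0.000196, and 0.275 with the estimate). In total 3426 probe sets were higher and 2738 lower, 2000 and 1591 of them at least 2-fold, but the total of 6164 changed to 1547 without FRI;FLC replicate 1. The balance of directions turned with it, to 664 higher and 883 lower, and likewise to 769 and 814 with array weights and to 171 and 417 with only the groups compared. With the mean of FRI;FLC days 4 and 9 as the control, a choice made after the data had been seen, the total was 3702. There the balance did not turn, with 1920 higher and 1782 lower.

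Genotype in 1 mm primordia was compared over 6 leaf positions, with 18 arrays of each genotype. AT1G69480 was again the largest named difference, at 5.60 ± 0.08 (adjusted p = 1.66e-35, higher at 6 of 6 positions). AGL42 was higher by 2.44 ± 0.06, in 4 of 6 positions, AT3G14395 by 2.57 ± 0.09, WSD1 by 2.03 ± 0.07 and AGL24 by 0.47 ± 0.06 (5 of 6). The AGL42 difference lay mostly at leaves 7, 9 and 11. Lower in FRI;flc-3 were the beta-glucosidase gene PYK10 (6.12 against 9.12), DFR (-2.07 ± 0.08), UF3GT (-1.68 ± 0.10) and AT4G14090 (-1.58 ± 0.10), each at 6 of 6 positions, and the MADS-box gene AGL19 (-1.10 ± 0.09, 4 of 6). All 3 flavonoid genes were lower (adjusted p = 5.48e-11, and 0.000267 with an estimated correlation, and 3 when adjusted over the list alone). Of the floral transition genes, 4 were higher and 1 lower (adjusted p = 0.00226 and 0.0326, also 4 and 1 when adjusted over the list alone). Glycosyltransferase genes gave 4 higher, among them UGT84A3 (1.63 ± 0.11), 14 lower and 25 not called, and that call was lost with an estimated correlation (adjusted p = 0.702). The 2132 probe sets called higher and 1983 lower included 84 and 99 with at least a 2-fold difference, so most of the 4115 were small differences. The total was 2547 without replicate 1 and 2549 without replicate 3. At full expansion, leaf 11 of FRI;flc-3 is a cauline leaf, so organ type and genotype were not separated at that position. Over the 5 rosette positions, a choice made after the data had been seen, 1039 probe sets were higher and 1226 lower, with AT1G69480 at 5.68, AGL42 at 1.71, AGL24 at 0.62, PYK10 at -2.23, DFR at -1.12 and AGL19 at -0.61.

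The change of primordia with leaf position, from leaves 1/2 to leaf 9, was measured with 3 arrays at each position. Leaves 1/2 were collected on day 6 and leaf 9 on day 16 in both genotypes, so position and plant age were not separated. In FRI;FLC, AGL24 rose by 7.29 ± 0.16 (adjusted p = 1.34e-29), from 2.32 to 9.61, AGL19 by 3.03 ± 0.22, the trichome patterning gene TRY by 1.80 ± 0.17 and DFR by 2.11 ± 0.20. EXPA8 fell by 5.04 ± 0.19, EXPB1 by 3.62 ± 0.21, MSRB5 by 4.70 ± 0.29 and the plastid gene rbcL by 1.84 ± 0.16. In FRI;flc-3, AGL24 rose by 7.66 ± 0.16, AGL42 by 7.26 ± 0.16 (adjusted p = 9.31e-30) and FD by 1.38 ± 0.20, while PYK10 fell by 6.50 ± 0.22 and AT1G69480 by 5.27 ± 0.21. For each of these genes the arrays of leaf 9 lay outside the range of leaves 1/2, which chance gives in 10% of splits of 3 against 3.

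Photosynthesis genes were called lower with position in primordia of both genotypes, but as lists only without an estimated correlation (with it, adjusted p = 0.149 and 0.227 for the plastid genes, 0.0605 and 0.114 for the nuclear genes). Of the plastid-encoded ones, 40 were lower and 3 not called in FRI;FLC, and 32 and 11 in FRI;flc-3. Of the nuclear ones, 23 were lower and 5 not called, and 21 and 7. The 4 photosynthesis genes fixed beforehand were all lower in both genotypes, also when adjusted over the list alone (adjusted p = 0.0129 and 0.0178, and 0.0975 and 0.125 with the estimate). In FRI;FLC, cell division genes were higher (16 higher, 0 lower, 12 not called, adjusted p = 0.000171, and 0.0352 with the estimate), as were nuclear RNA polymerase subunits (6 higher, 6 not called, 0.00655 and 0.0352), with BUB3.2 up by 1.13 ± 0.20 and NRPA2 by 0.95 ± 0.15. The 3 flavonoid genes were also higher there (adjusted p = 7.67e-05 and 0.015), and trichome genes gave 2 higher and 1 not called (0.0246 and 0.0491, and 3 higher when adjusted over the list alone), of which SIM (0.43 ± 0.15) had an adjusted p of 0.178 without replicate 2. Floral transition genes were higher in both genotypes, with 3 higher and 2 not called in FRI;FLC (adjusted p = 0.000499 and 0.015) and 4 and 1 in FRI;flc-3 (1.5e-07 and 0.000701), and the numbers over the list alone were 3 and 4. The counts were 3410 higher and 3262 lower in FRI;FLC, and 2802 and 2809 in FRI;flc-3.

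The effect of position in primordia differed between the genotypes for 539 probe sets, 361 more positive and 178 more negative in FRI;flc-3. AGL42 had the largest difference among the named genes, 6.59 ± 0.22 (adjusted p = 6.29e-23). It stayed between 2.01 and 2.81 from leaves 1/2 to leaf 9 of FRI;FLC, and in FRI;flc-3 it reached 4.37 at leaf 7 and 9.28 at leaf 9. AT4G34400 differed by 4.58 ± 0.32. PYK10 differed by -5.45 ± 0.32, AT1G69480 by -4.74 ± 0.29, AGL19 by -3.04 ± 0.31, DFR by -2.89 ± 0.28 and UF3GT by -2.27 ± 0.34. All 3 flavonoid genes were called lower (adjusted p = 1.58e-11, and 0.000192 with an estimated correlation, and 3 over the list alone), although AT4G14090 (-1.59 ± 0.35) reached 0.162 without replicate 3. Floral transition genes gave 3 more positive, 1 more negative and 1 not called (adjusted p = 0.000191 and 0.00939, and 3 and 1 when adjusted over the list alone), and FD, at 1.01 ± 0.29, had an adjusted p of 0.384 without replicate 3. The list of genes tied to vegetative phase change was called downward with 0 of its 9 genes called (adjusted p = 0.0468, and 0.305 with the estimate). Without replicate 1 the total was 242, and without replicate 3 it was 271.

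**Figure D3:**
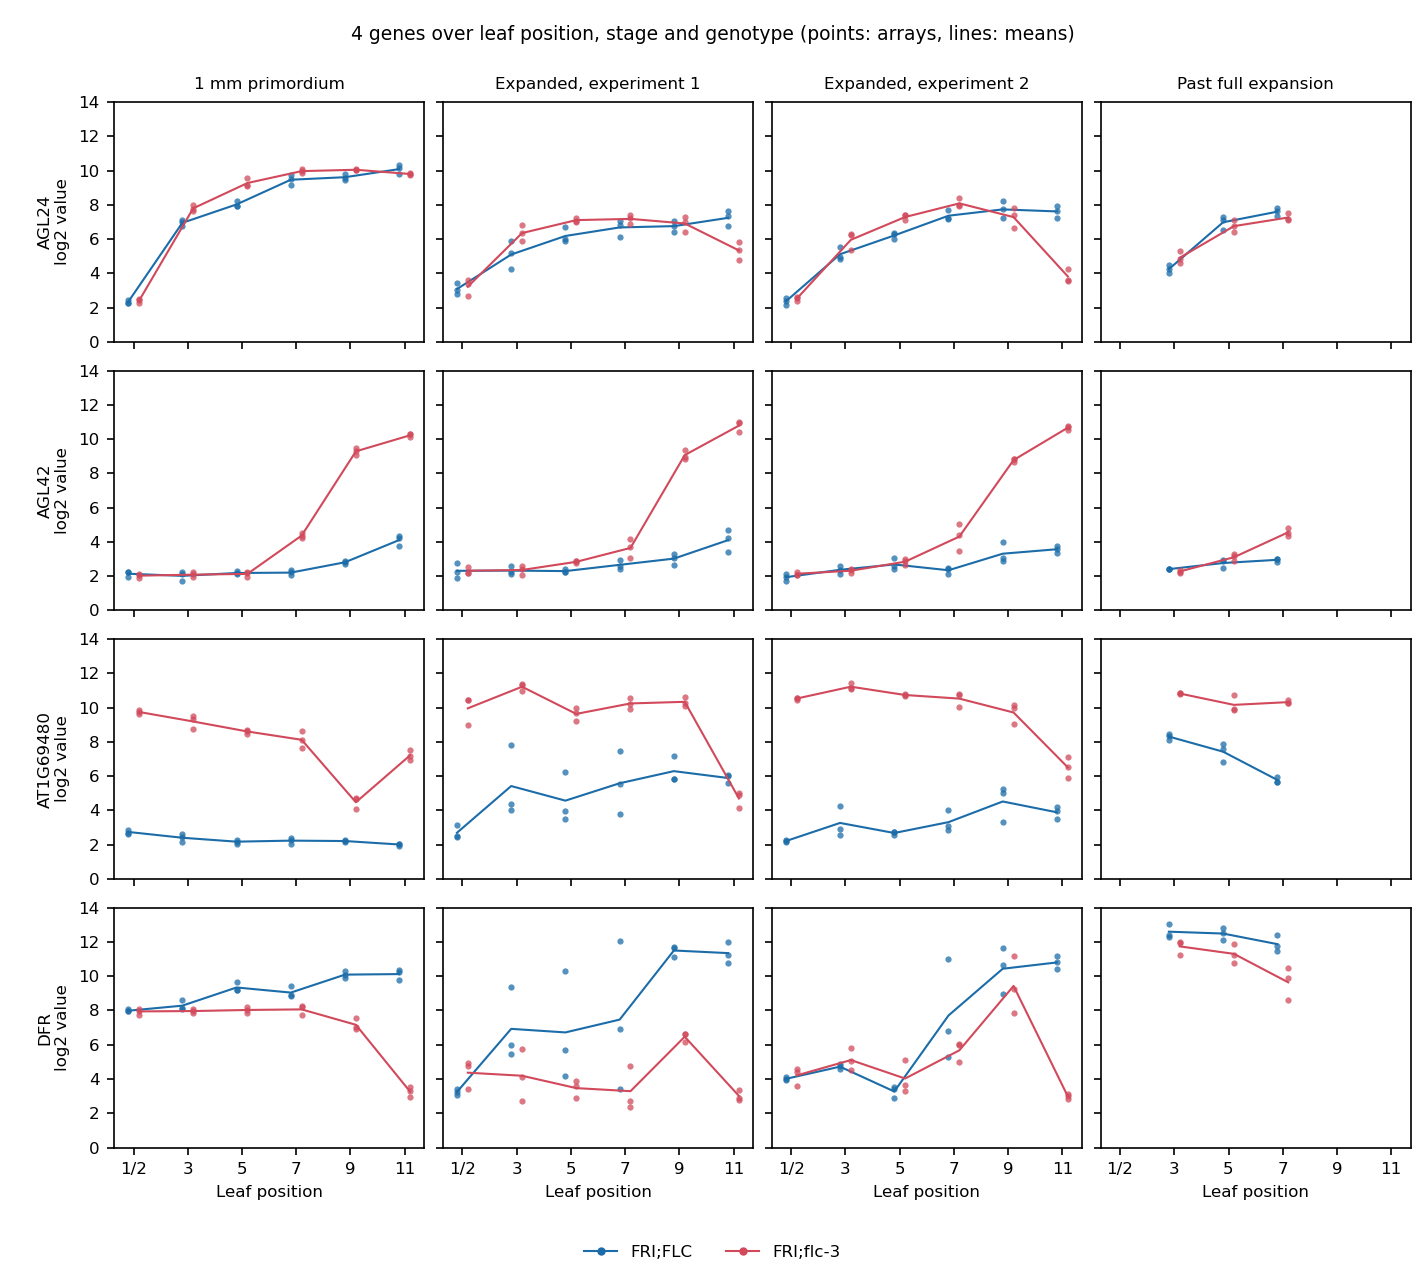
Log2 values of 4 genes against leaf position in 1 mm primordia, fully expanded leaves of each experiment and leaves past full expansion (points, arrays; lines, group means; blue, FRI;FLC; red, FRI;flc-3). AGL42 reached 9.28 in FRI;flc-3 primordia of leaf 9 and 2.81 in FRI;FLC, and DFR was 3.26 in the primordium of the cauline leaf 11 and 10.13 in FRI;FLC leaf 11.

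Genotype in fully expanded leaves was compared at leaves 1/2, 3, 5, 7 and 9 of both experiments, 30 arrays against 30. In experiment 1, FRI;flc-3 leaves 3, 5, 7 and 9 were collected on days 21, 24, 26 and 30 and those of FRI;FLC on days 23, 26, 29 and 33, so plant age and genotype are not separated there. AT1G69480 was higher in FRI;flc-3 by 6.36 ± 0.18 (adjusted p = 1.93e-40, 10 of 10 strata), with 5.37 in experiment 1 and 7.35 in experiment 2. AT1G03020 was higher by 3.45 ± 0.11 (3.73 and 3.16), the transcription factor gene bZIP44 by 1.77 ± 0.13 (1.70 and 1.84), AGL42 by 1.54 ± 0.08 (1.52 and 1.55, 9 of 10 strata) and AGL24 by 0.53 ± 0.10 (0.59 and 0.47, 9 of 10). The AGL42 mean was carried by leaf 9, with arrays from 8.69 to 9.38 in FRI;flc-3 and from 2.67 to 3.96 in FRI;FLC. At leaves 1/2 and 3 all arrays of both genotypes lay between 1.74 and 2.76, and leaves 5 and 7 differed less than leaf 9. EXLB1 was lower, at -1.75 ± 0.15 (-1.57 and -1.93), as were JAL23 at -1.67 ± 0.17 (-2.36 and -0.98) and COR15A at -0.68 ± 0.06 (-0.72 and -0.64). DFR differed by -1.58 ± 0.34, lower in 6 of 10 strata, and this rested on experiment 1 (-2.82, adjusted p = 7.11e-06), since in experiment 2 it was -0.34 (adjusted p = 0.716). DFR also rose past full expansion, by 6.53 ± 0.44, so the earlier collection of FRI;flc-3 leaves in experiment 1 is not separated from genotype for it.

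Floral transition genes were higher in expanded FRI;flc-3 leaves, with 4 called and 1 not, over the list alone as well (adjusted p = 0.000457, and 0.000991 with an estimated correlation). FD was among them at 0.29 ± 0.09, with an adjusted p of 0.12 without replicate 1. The 3 flavonoid genes were lower, also over the list alone (adjusted p = 0.0184, and 0.209 with the estimate). Cell division genes gave 0 higher, 10 lower and 18 not called, with POLA3 at -0.88 ± 0.14 and HTB2 at -0.67 ± 0.10, and cold and dehydration genes 0, 5 and 7; either call was lost with an estimated correlation (adjusted p = 0.473). Plastid-encoded photosynthesis genes gave 14 higher, 1 lower and 28 not called (adjusted p = 0.016, and 0.811 with the estimate). In total 3188 probe sets were higher and 3382 lower, 114 and 134 at least 2-fold. The total of 6570 was 3689 without replicate 3, and 5316 and 3001 in experiments 1 and 2 alone, with 1586 called in the same direction in both and 49 in opposite directions.

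The genotype difference of expanded leaves itself differed between the experiments for 621 probe sets, 378 more positive and 243 more negative in experiment 2. AT5G39520 differed by 3.81 ± 0.52, CML41 by 2.45 ± 0.40, the linker histone gene HIS1-3 by 1.62 ± 0.20 and AT1G69480 by 1.98 ± 0.37, and the tubulin gene TUB1 differed by -1.62 ± 0.22 and iqd21 by -1.64 ± 0.27, each in the same direction at 5 of 5 positions. Microtubule genes were called downward (0 higher, 6 lower, 36 not called, adjusted p = 2.41e-08, and 0.0206 with an estimated correlation). The flavonoid list was called upward with 2 higher and 1 not called (3 higher when adjusted over the list alone, adjusted p = 0.000487, and 0.074 with the estimate), but DFR (2.48 ± 0.68) had an adjusted p of 0.399 without replicate 2 and AT4G14090 (1.98 ± 0.52) of 0.223. The total of 621 was 214, 78 and 236 without replicates 1, 2 and 3.

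Leaf 11 compared a cauline leaf of FRI;flc-3 with a rosette leaf of FRI;FLC, 6 arrays against 6, so organ type and genotype were not separated. Plant age was not separated either. FRI;flc-3 was collected on day 30 and FRI;FLC on day 34 in experiment 1, and on days 32 and 33 in experiment 2. AGL42 was higher by 6.89 ± 0.18 (6.69 and 7.10 in experiments 1 and 2), AT1G03020 by 7.99 ± 0.25 (8.21 and 7.76), the green leaf volatile gene CHAT by 6.97 ± 0.37 (7.17 and 6.77) and WSD1 by 5.66 ± 0.40 (6.55 and 4.76). DFR was lower, at -8.08 ± 0.76 (-8.34 and -7.82), as were UF3GT at -4.78 ± 0.60, AT4G14090 at -5.94 ± 0.58 and the defensin gene PDF1.2 at -5.88 ± 0.75 (-6.03 and -5.74). Adjusted p values of these genes were at most 1.27e-09. The 3 flavonoid genes were all lower, also over the list alone (adjusted p = 7.86e-05, and 0.0732 with an estimated correlation), and division genes gave 2 higher, 13 lower and 13 not called (adjusted p = 0.0183 and 0.545). The unnamed probe sets 246531_at and 249867_at differed by 9.13 ± 0.21 and -8.02 ± 0.24. In total 3803 probe sets were higher and 3593 lower, and 2193 were called in the same direction in both experiments and 585 in opposite directions. The experiments differed here for 7888 probe sets, and their differences correlated at 0.328.

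The change of expanded FRI;FLC leaves from leaves 1/2 to leaf 9 was measured with 6 arrays at each position. Leaves 1/2 were collected on day 14 and leaf 9 on day 33 in both experiments, so position and plant age were not separated. DFR rose by 7.34 ± 0.76 (8.26 and 6.43 in experiments 1 and 2, adjusted p = 1.74e-12), HIS1-3 by 6.28 ± 0.22 (5.95 and 6.61), AGL24 by 4.52 ± 0.23 (3.67 and 5.37), LTI30 by 4.12 ± 0.29 (2.79 and 5.46) and the vacuolar processing gene BETA-VPE by 4.12 ± 0.32 (4.26 and 3.99). AT2G10940 fell by 7.11 ± 0.87 (7.24 and 6.99), BZIP61 by 5.88 ± 0.33 (5.50 and 6.26), EXLA1 by 5.09 ± 0.36 (5.46 and 4.72), PYK10 by 3.71 ± 0.43 (3.18 and 4.23) and the tetrapyrrole gene HEME1 by 2.03 ± 0.15 (1.79 and 2.27). PDF1.2 rose by 4.04 ± 0.75, but in experiment 1 alone its adjusted p was 0.12.

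Floral transition genes gave 4 higher and 1 not called with position in FRI;FLC leaves (adjusted p = 0.00116, and 0.00381 with an estimated correlation, and 4 over the list alone), and the 3 flavonoid genes were higher (adjusted p = 0.000853 and 0.086, and 3 over the list alone). Autophagy and vacuolar processing genes gave 10 higher, 0 lower and 3 not called (adjusted p = 1.27e-05 and 0.119), nuclear photosynthesis genes 2, 20 and 6 (1.51e-05 and 0.119), and jasmonate genes 6, 1 and 5 (0.0417 and 0.185). In total 4312 probe sets were higher and 4056 lower. The experiments differed here for 7277 probe sets, with 2471 called in the same direction in both and 598 in opposite directions, and experiments 1 and 2 alone called 5118 and 10115.

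In expanded FRI;flc-3 leaves over the same positions, AGL42 rose by 6.69 ± 0.18 (6.75 and 6.64 in experiments 1 and 2, adjusted p = 2.9e-41), HIS1-3 by 5.77 ± 0.22 (5.68 and 5.87), AGL24 by 4.23 ± 0.23 (3.69 and 4.77), LTI30 by 3.52 ± 0.29 (2.32 and 4.71) and FD by 1.62 ± 0.21 (1.81 and 1.44). XTH33 fell by 4.58 ± 0.41 (2.02 and 7.14), PYK10 by 3.88 ± 0.43 (3.58 and 4.18), the DNA polymerase subunit gene POLA3 by 2.93 ± 0.30 (2.90 and 2.96) and TUB1 by 2.71 ± 0.24 (2.04 and 3.37). All 5 floral transition genes were higher (adjusted p = 6.28e-08, and 1.5e-06 with an estimated correlation, and 5 over the list alone). Division genes gave 1 higher, 16 lower and 11 not called (0.000216 and 0.0467), autophagy genes 10, 0 and 3 (1.73e-06 and 0.0467) and beta-glucosidase genes 0, 9 and 9 (0.00776 and 0.0467). The 3 cell cycle genes were lower (adjusted p = 0.0363 and 0.0427, and 3 over the list alone), of which PRL fell by 2.44 ± 0.24, while AUR1 and AUR2 had adjusted p values of 0.0674 and 0.193 without replicate 3, and AUR2 of 0.216 without replicate 1. In total 4214 probe sets were higher and 4188 lower. Leaf 9 was collected later than leaves 1/2 (days 30 and 32 against day 14), so plant age was not separated from position. The total of 8402 was 5467 without replicate 2, 3730 in experiment 1 alone and 8509 in experiment 2 alone, and the experiments differed for 2264 probe sets.

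The effect of position in expanded leaves differed between the genotypes for 1259 probe sets, 623 more positive and 636 more negative in FRI;flc-3. This balance moved with the arrays, to 384 and 615 without replicate 2 and 653 and 311 without replicate 3. Leaves 1/2 were collected on day 14 in both genotypes. Leaf 9 followed on day 33 in FRI;FLC, and on days 30 and 32 of experiments 1 and 2 in FRI;flc-3. The shorter interval in FRI;flc-3 was not separated from genotype. AGL42 differed by 5.65 ± 0.26 (6.04 and 5.26 in experiments 1 and 2, adjusted p = 1.09e-27), CML41 by 4.85 ± 0.63 (3.56 and 6.14) and AT1G03020 by 4.85 ± 0.35 (5.26 and 4.43), and AT1G69480 differed by -3.17 ± 0.58 (-3.22 and -3.13). Floral transition genes gave 2 more positive and 3 not called (adjusted p = 4.74e-05, and 0.000166 with an estimated correlation, and 2 over the list alone), of which FD (1.08 ± 0.29) had an adjusted p of 0.348 without replicate 3. The 3 flavonoid genes were more negative (adjusted p = 0.00148 and 0.108, and 3 over the list alone), with DFR at -3.68 ± 1.08; in experiment 2 alone DFR was -1.20 (adjusted p = 0.791), and without replicate 1 it was -3.28 (0.265). PDF1.2, at -3.96 ± 1.06, had an adjusted p of 0.126 without replicate 3. The total was 578 without replicate 1, 824 in experiment 1 alone and 270 in experiment 2 alone.

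Leaves 3, 5 and 7 past full expansion were compared between the genotypes in experiment 2, 9 arrays against 9. FRI;FLC was collected on day 33 and FRI;flc-3 on day 32, so plant age was not separated from genotype. The methyltransferase gene BSMT1 was higher in FRI;flc-3 by 4.87 ± 0.57 (adjusted p = 2.01e-10), AT2G38240 by 5.10 ± 0.62 and AT1G03020 by 4.15 ± 0.20. EXLB1 was lower, at -4.97 ± 0.27, as were the sugar transporter gene SWEET4 (-3.74 ± 0.40), the cuticle regulator gene SHN3 (-3.40 ± 0.29), POLA3 (-2.07 ± 0.25) and the histone gene HTB2 (-1.50 ± 0.19). All of these held the same direction at 3 of 3 positions. Division genes gave 0 higher, 11 lower and 17 not called (adjusted p = 0.00502) and plastid-encoded photosynthesis genes 9, 0 and 34 (0.00402; psaA, 1.71 ± 0.37), and neither call held with an estimated correlation (0.282 and 0.616). None of the 8 fixed lists was called. In total 2781 probe sets were higher and 3339 lower, 609 and 588 at least 2-fold, and the total of 6120 was 3798 without replicate 1 and 3374 without replicate 2.

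Leaves past full expansion were set against leaves of the same positions and genotypes at full expansion, 18 arrays against 18 in 6 strata. DFR was higher by 6.53 ± 0.44 (adjusted p = 1.76e-20), UF3GT by 5.55 ± 0.35, SAG29 by 5.80 ± 0.32, BETA-VPE by 3.15 ± 0.18, the osmotin gene OSM34 by 3.03 ± 0.21 and WRKY6 by 1.50 ± 0.13. EXPA8 was lower, at -4.52 ± 0.29, as were BZIP61 (-3.94 ± 0.19), STOMAGEN (6.44 against 9.43), TUB1 (-1.51 ± 0.14) and HEME1 (-1.04 ± 0.08). Each of these genes had the same direction in 6 of 6 strata. WRKY53 was higher by 0.72 ± 0.23 in 4 of 6 strata, with an adjusted p of 0.147 without replicate 3, and differed by 1.47 in FRI;FLC and -0.02 in FRI;flc-3.

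In leaves past full expansion, all 3 flavonoid genes and 3 of the 4 senescence genes were higher (adjusted p = 1.4e-06 and 0.00208, and 0.00924 for either with an estimated correlation). The 3 cell cycle genes and 2 of the 4 stomata genes were lower (adjusted p = 0.0373 for either, and 0.0414 with the estimate), and these 4 counts were the same when adjusted over each list alone. AUR2, in the cell cycle list, had an adjusted p of 0.211 without replicate 3. Nuclear photosynthesis genes gave 1 higher, 24 lower and 3 not called (adjusted p = 1.11e-08 and 0.0259). Cold and dehydration genes gave 9 higher, 2 lower and 1 not called, and microtubule genes 3, 25 and 14, with an adjusted p of 0.0655 with the estimate for either. In total 4154 probe sets were higher and 4241 lower, of which 817 and 573 differed at least 2-fold.

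The change past full expansion differed between the genotypes for 1352 probe sets, 666 more positive and 686 more negative in FRI;flc-3. Leaves past full expansion were collected on day 33 in FRI;FLC and day 32 in FRI;flc-3. At full expansion, leaves 3, 5 and 7 were collected on days 23, 26 and 29 in both genotypes. The interval was thus shorter in FRI;flc-3 and was not separated from genotype. BSMT1 differed by 4.21 ± 0.81, the thionin gene THI2.2 by 3.26 ± 0.48, UGT76D1 by 2.70 ± 0.27, the auxin conjugation gene WES1 by 2.42 ± 0.41 and BGLU16 by 1.23 ± 0.22, and AT1G69480 differed by -4.48 ± 0.47, EXLB1 by -3.28 ± 0.38 and SHN3 by -2.95 ± 0.42 (highest adjusted p = 0.000242, for BSMT1, 3 of 3 positions in each). SWEET4, at -2.51 ± 0.57, had an adjusted p of 0.123 without replicate 1. Auxin genes gave 4 higher, 0 lower and 14 not called, and glycosyltransferase genes 8, 2 and 33 (adjusted p = 0.0174 for either), and neither was called with an estimated correlation (0.111 and 0.234). The total was 418 without replicate 1 and 294 without replicate 2.

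Expanded leaves of experiment 1 were set against primordia of the same positions and genotypes, 30 arrays against 30 in 10 strata. BCAT4 was higher in expanded leaves by 9.11 ± 0.09 (adjusted p = 2.89e-62), the ubiquitin ligase gene RING1 by 7.68 ± 0.11, CYP71B23 by 6.63 ± 0.12 and UGT72E1 by 5.80 ± 0.08. The Aurora kinase genes AUR2 and AUR1 were lower, at -7.33 ± 0.08 and -6.41 ± 0.06, as were the chromosomal protein gene 3xHMG-box2 (-8.16 ± 0.11), the topoisomerase gene TOPII (-7.32 ± 0.08), MUTE (-4.17 ± 0.08), SPCH (-4.10 ± 0.08) and the RNA polymerase I subunit gene NRPA1 (-2.85 ± 0.11). Each of these genes had the same direction in 10 of 10 strata.

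Of the division genes, 1 was higher in expanded leaves, 27 were lower and 0 were not called (adjusted p = 9.28e-11, and 2.02e-05 with an estimated correlation). All 3 cell cycle genes (adjusted p = 0.0145 and 0.0223) and all 4 stomata genes (0.0288 and 0.0355) were lower, also over the list alone. CYP71B genes gave 11 higher, 2 lower and 2 not called (0.00446 and 0.0244). Autophagy genes gave 13 higher and 0 lower, jasmonate genes 11 and 0, plastid-encoded photosynthesis genes 40 and 0, and nuclear RNA polymerase subunits 0 and 11, with adjusted p values of 0.079, 0.079, 0.464 and 0.116 when the correlation was estimated. In total 8260 probe sets were higher and 8743 lower, 3687 and 4111 of them at least 2-fold.

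**Figure D4:**
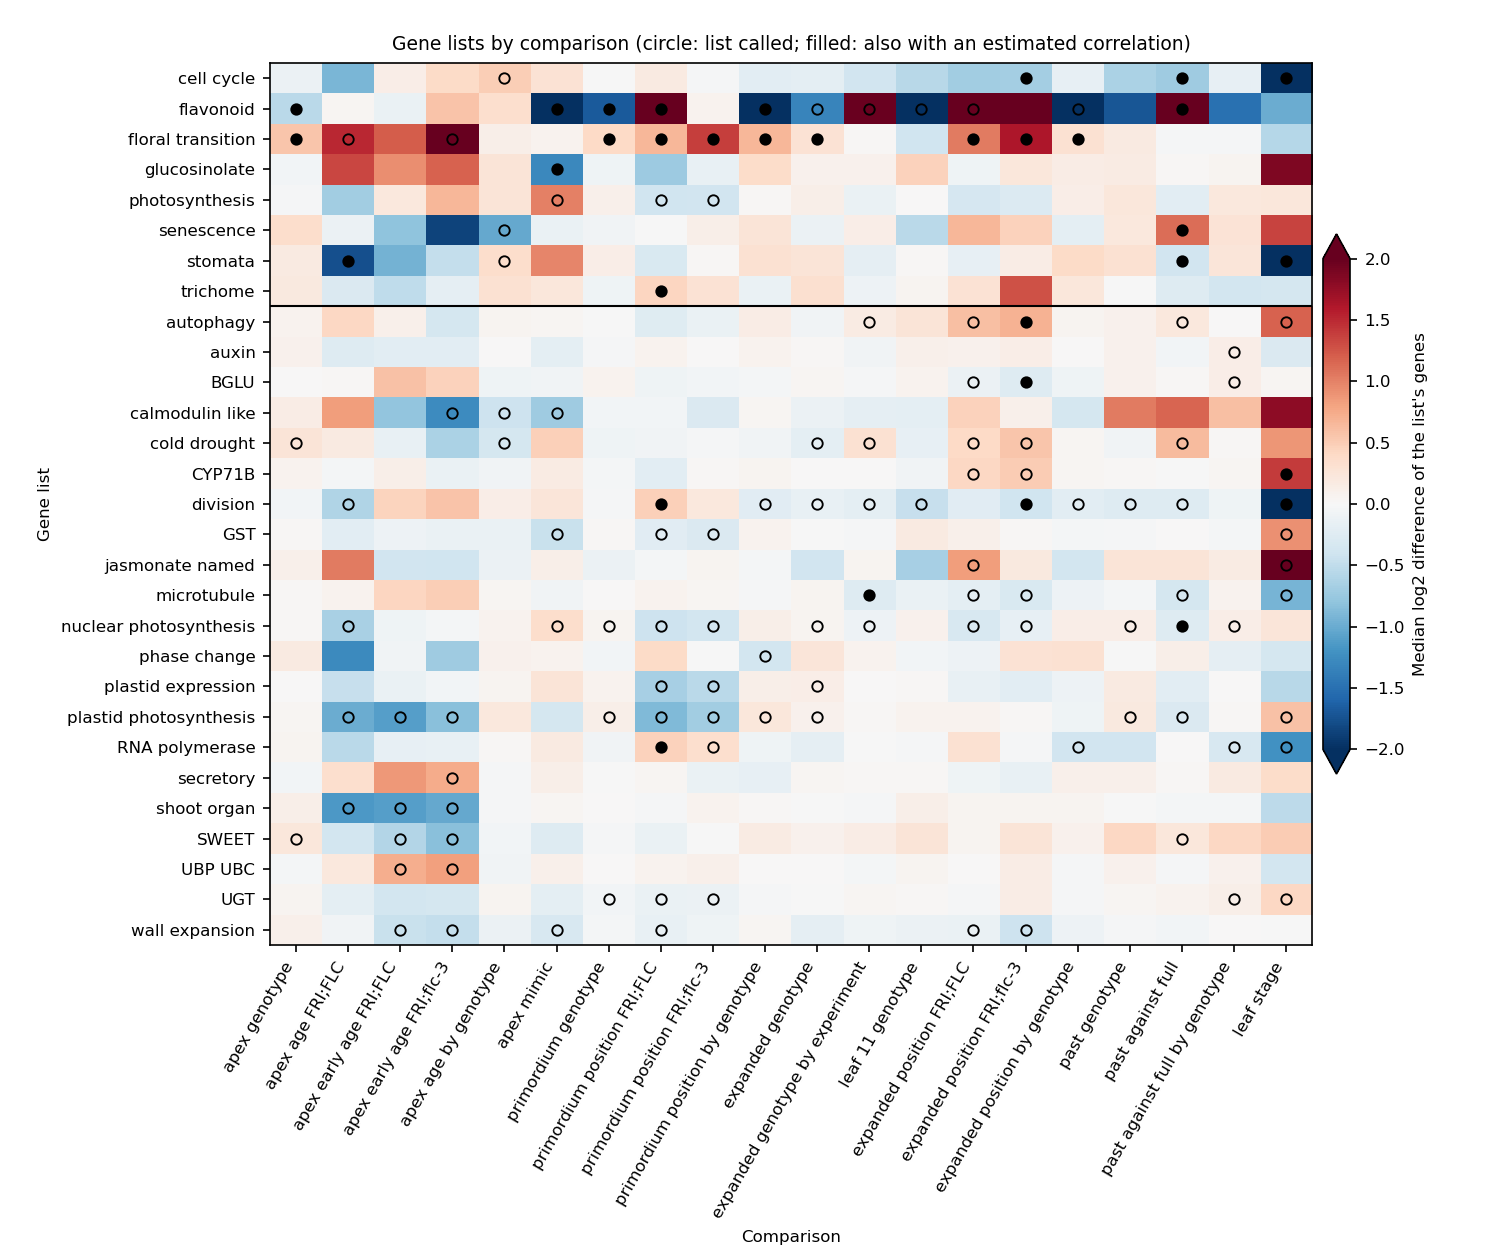
Median log2 difference (colour scale) of the genes of each list reported here that was fixed beforehand and tested or had a call in some comparison (y axis), for each comparison (x axis); circles mark called lists and filled circles those also called with an estimated correlation. Floral transition genes were called with the estimate in 9 comparisons.

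Some genotype differences were common to all organs. In apices, primordia, expanded leaves and leaves past full expansion, 26 probe sets were called higher in FRI;flc-3 and 10 lower, against 0.37 and 0.23 expected from the separate counts. That expectation treats these organs as independent, although they came from the plants of only 2 experiments. AT1G69480 was higher by 4.83, 5.60, 6.36 and 3.26 in this order and FD by 0.76, 0.39, 0.29 and 0.45, while the unnamed probe set 260037_at differed by -4.61, -6.14, -6.22 and -5.93. As given above, FD lost its call in apices and in expanded leaves with some replicate left out. The apex total, on which this overlap rests, also fell then. Across probe sets, which are not independent replicates, the genotype differences of expanded leaves and leaves past expansion correlated at 0.65, those of primordia and expanded leaves at 0.40, and those of apices and primordia at 0.23. The correlation was 0.19 for primordia and leaves past expansion, 0.053 for apices and expanded leaves and 0.019 for apices and leaves past expansion. Of the probe sets called in both members of these 6 pairs, 96.8%, 86.7%, 90.7%, 74.4%, 75.2% and 66.7% had the same direction. For apices and leaves past expansion, 33 were called in opposite directions, against 35.2 by chance. The mimic difference of apices correlated with the position change of FRI;FLC primordia at 0.174. Of the calls, 739 were higher in both against 605 by chance, 733 lower in both against 462, and 1017 in opposite directions against 1061. The age change of FRI;FLC apices correlated with that position change at 0.177. It gave 965 higher in both against 858, 1318 lower in both against 814, and 1385 in opposite directions against 1672. The same direction held for 59.1% of the probe sets called in both for the mimic and 62.2% for age. The overlap was thus not particular to the mimic line, whose control arrays also differed from each other.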

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

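The splits after removal of a common effect, the removal of length trends and the correlation with the change past full expansion were tests chosen only after the data or the result were seen. The comparisons here are those that test a difference between 2 groups' effects. The threshold was applied to single probe sets, and each gene named for these comparisons passed it. No group had between 4 and 10 arrays, so single arrays were not tested against their group by this route.

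The change of apices from day 4 to day 11 differed between the genotypes for 92 probe sets, and for 31, 25 and 8 without replicates 1, 2 and 3. The difference was positive, a more positive change in FRI;flc-3, for AT4G34400 (3.30), WSD1 (2.40), AT3G47250 (2.12), AT5G44630 (2.00), AT5G15780 (1.89) and AT3G19550 (1.82). It was negative for LTI30 (-4.21), AT2G37870 (-3.05), AT2G17850 (-2.57), AT5G40450 (-2.50), CML38 (-2.50) and AT1G69480 (-2.48). Of 100 splits of the arrays, 2 gave as many calls, the real one included, and the highest other 143. Such splits exchange arrays between genotypes (between experiments for the comparison of experiments), so an effect common to both ends of a difference can enter their counts. With that common effect removed, 1 of 100 splits gave as many calls and the highest other 14, which argues against chance.

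The position change of primordia differed between the genotypes for 539 probe sets, and for 242 without replicate 1 and 271 without replicate 3. AGL42 (6.59), AT2G17280 (4.74), AT4G21650 (4.65), AT4G34400 (4.58), AT3G14395 (4.41) and AT4G19430 (3.99) had the largest positive differences among the named genes. The largest negative ones were those of PYK10 (-5.45), AT1G69480 (-4.74), AT1G31710 (-3.44), AT1G19960 (-3.05), AGL19 (-3.04) and AT4G19380 (-2.91). Of 100 splits, 11 gave as many calls and the highest other 1206, so the splits planned beforehand did not exclude chance. The genotype difference itself can enter their counts. With the common effect removed, a step added later, 1 of 100 splits gave as many and the highest other 69. That argues against chance, but by the later step alone.

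In expanded leaves the genotype difference was unlike between the experiments for 621 probe sets, and for 214, 78 and 236 without replicates 1, 2 and 3. It was more positive in experiment 2 for AT5G39520 (3.81), CML41 (2.45), AT1G69480 (1.98), AT1G53100 (1.77), HIS1-3 (1.62) and AT2G41190 (1.50). It was more negative there for AT2G10940 (-3.25), AT1G09750 (-1.85), AT3G12710 (-1.84), AT4G28780 (-1.66), iqd21 (-1.64) and TUB1 (-1.62). Of 100 splits, 3 gave as many calls, with 1419 as the highest other count. Once the common effect was removed, 1 of 100 did, with 2 as the highest other count, which argues against chance.

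The position change of expanded leaves differed between the genotypes for 1259 probe sets, and for 578 without replicate 1, 824 in experiment 1 alone and 270 in experiment 2 alone. Positive differences were found for AGL42 (5.65), CML41 (4.85), AT1G03020 (4.85), AT3G62960 (4.27), AT1G13650 (4.23) and AT3G62950 (4.22), and negative ones for AT4G16260 (-4.10), PDF1.2 (-3.96), DFR (-3.68), AT1G69480 (-3.17), THI2.1 (-3.09) and AT4G14090 (-2.96). Of 100 splits, 3 gave as many calls, with 1993 as the highest other count. Once the common effect was removed, 2 of 100 did, and the highest other count of 2517 exceeded the real one. Such counts were rare among the splits, but chance is not excluded for this total.

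The change past full expansion differed between the genotypes for 1352 probe sets, and for 418 without replicate 1 and 294 without replicate 2. AT2G38240 (5.33), BSMT1 (4.21), AT1G74010 (3.75), THI2.2 (3.26), AT3G61930 (3.04) and AT4G18425 (2.96) changed more positively in FRI;flc-3. AT1G69480 (-4.48), AT3G53980 (-3.49), EXLB1 (-3.28), AT2G37870 (-3.18), SHN3 (-2.95) and SWEET4 (-2.51) changed more negatively. Among 100 splits, 2 were as large, with 1417 as the highest other count. Once the common effect was removed, 1 of 100 was, with 113 as the highest other count, which argues against chance.

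The 621 probe sets whose genotype difference was unlike between the experiments were weighed further, because experiment 1 collected FRI;flc-3 leaves earlier than FRI;FLC leaves. Gene length is argued against as the whole cause, since among genes with a length 337 were called after each array's trend on length was removed and 278 before, 253 of them in both. A candidate explanation is leaf or plant age at collection: across probe sets the difference between the experiments correlated at 0.653 with the change past full expansion, and 95.0% of the calls went the same way (0.866 across the called ones). At leaves 1/2, collected on equal days, the correlation was -0.0184, and at leaves 3, 5, 7 and 9, collected 2 or 3 days apart in experiment 1 and at most 1 day apart in experiment 2, it was 0.369 to 0.596, but leaves 3, 5 and 7 share their full-expansion arrays of experiment 2 with the change past full expansion, while leaf 9 (0.369) and leaves 1/2 share none. Growth conditions that differed between the experiments, and their interplay with genotype, stay open as untested.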

How the results depend on the processing

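The following settings were chosen only after the data were seen: the 5 rosette positions of primordia, the mean of days 4 and 9 as the control of the mimic line, fits without certain arrays, and the removal of trends on gene length. Of the counts recomputed under another setting, 203 stayed within 1.5 times their reported value and 57 moved beyond it. Of the values of named genes, 7351 kept their direction and their side of the threshold, 288 lost the call, 25 gained it and 5 changed sign. Named genes were largely chosen as large differences in these same arrays, so this tally is no independent measure of their stability. For the gene lists reported here, 98 tests kept direction and call and 133 kept the direction without the call. The 20 counts among genes with a length all stayed within 1.5 times when the trend on length was removed. Quantile normalization moved the median of all differences by at most 0.09 in size (-0.09, early age change of FRI;flc-3). With it, without an intensity trend, with a robust prior and with the replicate number as a block, all counts stayed within 1.5 times. The deviations of arrays with the same number correlated on average at 0.0647 in apices, -0.00117 in primordia and 0.0167 in leaves, and 21 of 29, 12 of 36 and 42 of 90 arrays lay closest to their own number. Same-number pairs correlated above 0.1 in 45.2% of cases in apices, 20.7% in primordia and 34.4% in leaves. Not every pair was alike and the labels state no pairing, so the numbers were not taken to pair the arrays. The apices hint at it, and the leaves to a lesser degree.

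With only the probe sets above the median signal, fewer were tested, and the counts were 65 for apex genotype, 5231 for apex age FLC, 6305 for apex early age FLC, 6420 for apex early age flc-3, 12 for apex age by genotype and 3685 for apex mimic. For primordium genotype the count was 2026, for primordium position FLC 4025, for primordium position flc-3 3349 and for primordium position by genotype 146. In leaves it was 4029 for expanded genotype, 342 for expanded genotype by experiment, 4220 for leaf 11 genotype, 4969 for expanded position FLC, 4710 for expanded position flc-3, 755 for expanded position by genotype, 3643 for past genotype, 4612 for past against full, 651 for past against full by genotype and 8760 for leaf stage.

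Array weights gave 464 calls for apex genotype, 1583 for apex mimic, 1375 for expanded genotype by experiment, 3288 for expanded position by genotype and 4026 for past against full by genotype; the cause was not tested, and the weights did not reach their convergence tolerance in every fit. With only the arrays of the groups compared, which are fewer, apex age by genotype gave 55 and apex mimic 588. Day 6 added to apex genotype gave 618, and without the day 6 arrays of FRI;FLC and FRI;flc-3 apex genotype gave 358 and apex age by genotype 203; the cause was not tested. The mean of days 4 and 9 as the control gave 3702 for apex mimic, and the 5 rosette positions, with fewer arrays, 2265 for primordium genotype. Experiment 2 alone gave 3001 for expanded genotype and 270 for expanded position by genotype, and experiment 1 alone 5118 for expanded position FLC, 3730 for expanded position flc-3 and 824 for expanded position by genotype. Fewer arrays are not the whole cause, because the other experiment alone gave 5316 for expanded genotype, 10115 for expanded position FLC and 8509 for expanded position flc-3, and what else differs between the experiments was not tested.

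Leaving out each replicate in turn, which also means fewer arrays, gave 56 to 189 calls for apex genotype, 8 to 31 for apex age by genotype, 1547 to 8896 for apex mimic, 2547 to 3109 for primordium genotype and 242 to 388 for primordium position by genotype. In leaves the ranges were 3689 to 5486 for expanded genotype, 78 to 236 for expanded genotype by experiment, 5467 to 7784 for expanded position flc-3, 578 to 999 for expanded position by genotype, 3374 to 6299 for past genotype and 294 to 1494 for past against full by genotype. Where such an omission left 1 array in a group, that array was assumed to vary like the other groups.

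For the values that changed sign, the cause was not tested. AUR1 in apex age by genotype (0.26) ranged from -0.058 to 0.60 over the omitted replicates. GSTU22 in apex mimic (-0.81) was 0.080 with the control of days 4 and 9, CYP71B23 in expanded position flc-3 (1.72) was -0.29 in experiment 1 alone, NRPC2 in expanded position by genotype (-1.04) was 0.15 in experiment 2 alone, and WRKY53 in past against full (0.72) was -0.022 in FRI;flc-3 alone. Lists with fewer than 3 genes left above the median signal had no value there. Signal on arrays bounds small changes near the background, and the number of arrays limits the differences of changes. With noise independent between probe sets, simulated changes of 1 log2 unit were recovered in 18% of cases for apex age by genotype. For expanded genotype the recovery was 100%.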

Other observations

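The removal of length trends and the tests of an advance in age of the mimic apices, of a shared collection of replicates of 1 number and of leaves unlike in age were chosen only after the data or the result were seen, as were the genes of the next 2 paragraphs. In 1 mm primordia the MADS-box genes followed different courses along the shoot. AGL24 averaged 2.32, 6.94, 8.02, 9.46, 9.61 and 10.08 at leaves 1/2, 3, 5, 7, 9 and 11 of FRI;FLC and 2.39, 7.79, 9.27, 9.96, 10.04 and 9.80 in FRI;flc-3, so most of its rise lay between the first pair of leaves and leaf 3. AGL42 stayed near 2 up to leaf 5 in both genotypes, and at leaf 11 it stood at 4.11 in FRI;FLC and 10.22 in FRI;flc-3. AGL19 rose from 2.64 to 5.87 over these positions in FRI;FLC, whereas in FRI;flc-3 it went from 3.09 to 3.85 at leaf 5 and back to 2.32 at leaf 11. In fully expanded leaf 11, AGL24 averaged 7.24 and 7.61 in FRI;FLC and 5.33 and 3.82 in the cauline leaf of FRI;flc-3, in experiments 1 and 2.

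AT1G69480 fell in FRI;flc-3 primordia from 9.75 at leaves 1/2 to 4.48 at leaf 9 and was 7.22 at leaf 11, while it did not exceed 2.74 in any FRI;FLC primordium group. In FRI;FLC leaves 3, 5 and 7 it stood at 3.27, 2.68 and 3.32 at full expansion in experiment 2 and at 8.31, 7.43 and 5.78 past it. PYK10 reached 2.05 in FRI;flc-3 primordia of leaf 11, against 8.89 in FRI;FLC, and in apices it stayed between 11.27 and 11.84 in both genotypes and was 9.20 in the mimic line. In day 6 apices of the mimic line FD averaged 4.98 and AGL42 4.51, against 2.33 and 2.21 in FRI;FLC, and AGL24 averaged 5.08 against 6.67.

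The mimic line gave 6164 calls against 2 control arrays that themselves correlated at only 0.954. Gene length is argued against as the whole cause, because among genes with a length 3174 were called after each array's trend on length was removed and 3220 before, 2266 of them in both. Without FRI;FLC day 6 replicate 1 the calls numbered 1547, and 8896 without replicate 2, but which control array stands apart remains open: replicate 1 shared the deviation of the FRI;flc-3 array of day 6 from days 4 and 9 (r = 0.762) more than replicate 2 did (0.275), and the length slopes were -1.41 and 0.06 in replicates 1 and 2 and -1.44 in the FRI;flc-3 array. The mimic apices may be ahead in age, since their difference correlated at 0.437 with day 9 minus day 4 of FRI;FLC (0.380 with the length trend removed), but so did the difference between the 2 control arrays, at 0.629. An array off its group and an advance in age stay open, as does the direct effect of lower miR156 activity, which the design names and these tables do not separate from them.

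In expanded leaves and leaves past full expansion, 1 axis carried 34.7% of the variance within groups, and the next 6.61%. The axis score followed the array median (r = 0.785) and the array's slope on length (0.984), and a difference that quantile normalization removes is argued against, because the share was 34.4% after it, and so, as the whole cause, is a shared collection of arrays with the same replicate number, whose deviations correlated on average at 0.0167, against -0.00834 for unlike numbers. A trend with gene length may be part of it: the loadings correlated with length at 0.534 (Spearman), the 500 genes at either end had median lengths of 1359.5 and 3945 bp, and removing each array's trend took the share from 35.1% to 27.7%. What makes the trend differ between arrays, such as the state of the RNA or its amplification, stays open. Leaves of a group that were unlike in age stay open as well, since the loadings of the axis in expanded leaves of experiment 1 correlated with the change past full expansion at 0.299 in size, and at 0.293 with the length trend removed from both.

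Other splits of the arrays were counted for the remaining comparisons. Chance is argued against for apex genotype (216 calls, highest other split 27), primordium genotype (4115 and 1058), expanded genotype (6570 and 204), expanded position in FRI;flc-3 (8402 and 6927), past genotype (6120 and 2301), past against full (8395 and 2085) and leaf stage (17003 and 12450), with 1 of 100 splits as large in each. For leaf 11 (7396 and 8527) 4 of 100 were as large, and for expanded position in FRI;FLC (8368 and 10012) 2 of 100 were. In these 2 comparisons another split gave more calls than the real one, so chance is not excluded. The shares were not adjusted over the comparisons. The 10 splits of 3 arrays against 3 cannot give a share under 0.05. Real and highest other counts were 9686 and 1 for apex age in FRI;FLC, 11673 and 0 and 11595 and 0 for the early age changes of FRI;FLC and FRI;flc-3, and 6672 and 0 and 5611 and 0 for the position changes of primordia.

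Across genes, the early age changes of apices correlated with gene length at 0.412 in FRI;FLC and 0.451 in FRI;flc-3, and the genotype difference of apices at -0.329. The correlation was 0.389 for the mimic difference and 0.292 for genotype in expanded leaves. For expanded position it was -0.266 in FRI;FLC and -0.262 in FRI;flc-3, and elsewhere at most 0.232 in size. The 2 most extreme arrays at the low end of the axis in leaves were the third replicates of FRI;FLC leaves 11 and 9 of experiment 1 (scores -71.9 and -70.5).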
